A study of Caenorhabditis elegans with 2 samples.

How the data were processed

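Binding of SNPC-4, a subunit of the small nuclear RNA activating protein complex (SNAPc), was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) of an eGFP-tagged protein in whole young adult Caenorhabditis elegans of pooled sex. Per the labels, the worms were strain OP179, which carries the integrated transgene wgIs179 in an unc-119 mutant. The labels give 1 group of 2 biological replicates with library fragments of 150 to 350 bp. The starting point was the authors' peak lists on 2 genome builds, ce10 and ce11, with 4 lists per build: a relaxed list for each replicate, a relaxed list for the pooled reads, and the optimal list left after filtering by the irreproducible discovery rate (IDR). Per the labels, the relaxed lists were called against a control, and no control library was analysed here. The aligner, the peak caller and the IDR threshold were not given in the sources used here. The depth of each library is unknown, so no interval or floor based on reads is given, and intervals cover the counting of peaks or genes only.

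Each deposited peak carries the signal value of the authors' caller, a -log10 q value and a summit position, in the column order of the narrowPeak format. The authors' signal values were used within each list, and values of different lists were compared by ranks or by matched peaks. The deposited -log10 q value was the same for every peak of the optimal list and was not used for ranking. The optimal list was checked against the pooled relaxed list on ce11: all 1781 optimal peaks had the same summit and signal there, and together they were the 1781 strongest pooled peaks. Main results used the ce11 optimal list, because ce11 is the assembly of the reference annotation. No coordinates were converted between builds, and the chromosome comparison on ce10 used the ce11 chromosome lengths.

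The annotation held 46890 genes, which were placed in 10 classes by gene biotype and symbol: 99 small nuclear RNA (snRNA) genes, 31 spliced leader (SL) RNA genes, 612 tRNA, 20 rRNA, 346 small nucleolar RNA (snoRNA), 261 microRNA (miRNA), 15363 Piwi-interacting RNA (piRNA, called 21U-RNA in this species), 8058 other non-coding RNA, 19973 protein-coding genes and 2127 pseudogenes. A gene was counted as having a peak when an optimal summit lay within 300 bp of its annotated 5' end. For comparisons of signal, each peak was placed in 1 class by a fixed order that put the small RNA classes ahead of protein-coding genes. Windows rich in 21U-RNA genes were 100 kb windows with at least 50 annotated 21U-RNA genes, and windows less than 500 kb apart were joined into regions.

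Enrichment of peaks near a class, and the share of peaks in the 21U-RNA-rich windows, were tested by rotating all summits along each chromosome 10000 times, which keeps the spacing of the peaks. These p-values are two-sided and cannot be smaller than 0.0002. Shares of genes with a peak were compared with protein-coding genes by two-sided Fisher's exact tests. Peaks per chromosome were compared with chromosome length by two-sided exact binomial tests. Median signal was compared with protein-coding peaks by two-sided permutation tests with 100000 resamples, whose smallest p is 2e-05, for classes of 10 or more peaks. The core motif of 21U-RNA genes, CTGTTTCA, was searched on both strands within 100 bp of summits and compared with points 1000 bp to each side by exact McNemar tests. The replicates were compared by the share of optimal summits within 200 bp of a summit in each replicate's own list, cut at the optimal list's length by signal, with 1000 rotations for chance. Shares carry 95% Clopper-Pearson intervals. Benjamini-Hochberg adjustment was applied within each family of tests (classes, chromosomes, gene lists, snRNA families, tRNA groups), and the threshold was an adjusted p of 0.05. The unit of every p-value is a peak or a gene, not an animal, since 2 replicates of 1 group allow no test between samples. Neighbouring genes and near-identical gene copies are not independent.

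The distances, thresholds, classes and tests of the main comparisons, 15 gene lists and the rule for naming genes were fixed before the data were examined. The rule named the genes of the 20 strongest peaks, up to 3 members of each class and of each list with the strongest peaks, snpc-4 and unc-119, and the strongest peak of each 21U-RNA-rich region. Genes named outside the rule are marked in the text as chosen after their values were seen. Splits of snRNA, SL RNA, tRNA and 21U-RNA genes into families or places were added later, as were the joining of windows into regions, the correlation across windows of chromosome IV, the comparisons of motif with signal and with genes, the rotations of summits within the joined 21U-RNA-rich windows, the tRNA shares in the relaxed lists, the search for shared upstream 36-mers and the snRNA families without them, the count of distinct peaks in each gene list, and the 22 bp promoter element. That element was learned by expectation maximisation from the 120 bp upstream of 145 snRNA, SL RNA and snoRNA genes with a peak, after a ranking of 8-mers. A peak carried the element when its best score near the summit exceeded 95% of the best scores at points 1000 bp to the sides, a threshold of 5.72 in log2 odds. Families of snRNA genes were assigned by a conserved stretch of each RNA.

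Alternatives covered distances of 150, 500 and 1000 bp, the stronger 50% of peaks, each replicate left out, random placement of summits, other comparison genes, other window and motif settings, other matching rules and ce10. The set of peaks matched in both replicates' lists was added after the data were seen. The scripts were tested on simulated data: peaks planted at snoRNA genes passed in 100% of lists, and random peak lists passed for protein-coding genes in 3% of lists and for any single class in at most 8%. The symbol snpc-1.5 was not in the annotation, and snpc-3.3 and prg-2 are pseudogenes there, so all 3 were left out of their lists. The lists held no peaks on the mitochondrial genome. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.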

Results

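The data are peak lists of SNPC-4 binding in whole young adult worms, from 1 group of 2 biological replicates. SNPC-4 is a DNA-binding subunit of SNAPc, the complex that recruits RNA polymerase II or III to small nuclear RNA promoters. The optimal list on ce11 held 1781 peaks with a median width of 324 bp and signal values from 31.1 to 1801 (median 42.6). The relaxed lists held 20730 peaks in replicate 1, 30000 in replicate 2 and 30000 in the pooled reads. On ce10 the optimal list held 1832 peaks. Read depth is unknown, and p-values describe peaks or genes, not animals. Signal values of the optimal list come from the pooled reads and carry no error between replicates.

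The first comparison asked which genes the strongest peaks lay beside. Of the 20 strongest peaks, 17 lay within 300 bp of the 5' end of an snRNA, SL RNA or snoRNA gene, and the other 3 lay beside 2 other non-coding RNA genes and the miRNA gene mir-2214. The highest signal of the list, 1801, stood 75 bp upstream of the snoRNA gene Y53F4B.47 (chromosome II, peak from 15025740 to 15026183), with 608 in replicate 1 and 1174 in replicate 2. This peak also lay 146 bp upstream of the protein-coding gene cmtr-1. The snoRNA gene ZK994.7, inside an intron of pxn-1 on chromosome V, followed at 1501. W05B2.8, an snRNA gene of the U6 family inside an intron of dhc-4, reached 1472, and the SL2 RNA genes sls-2.4 and sls-2.8 reached 1277 and 1209.5. The gene rpr-1, which encodes the RNA subunit of RNase P, had a peak of 1101 with its summit 19 bp upstream of the 5' end. Among the 100 strongest peaks, 67 were assigned to the snRNA, SL RNA, tRNA or snoRNA class, 8 to protein-coding genes and 2 to 21U-RNA genes.

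SNPC-4 peaks lay near the 5' ends of small RNA genes far more often than rotated peaks did. SL RNA genes had 19 peaks within 300 bp, 54.3 times the rotation mean. The corresponding values were 48 peaks and 37.5-fold for snRNA genes, 86 peaks and 23.4-fold for snoRNA genes, and 109 peaks and 20.9-fold for tRNA genes. Other non-coding RNA genes had 280 peaks (4.27-fold), protein-coding genes had 687 (3.38-fold), and 21U-RNA genes had 368 (2.45-fold). These 7 of 10 classes passed the threshold, with an adjusted p of 0.000571 for 21U-RNA genes and 0.000333 for each of the others. Genes for miRNA (6 peaks, 2.28-fold, adjusted p = 0.12) and rRNA (1 peak, beside rrn-4.15, adjusted p = 0.254) did not pass this permutation test by rotation. Of the 20 rRNA genes, 17 share a 36-mer of their 200 bp upstream sequence with another place in the genome, 12 of them over its whole length, so the rRNA count is not evidence of less binding. Pseudogenes were at 0.724-fold with 16 peaks and did not pass either (permutation by rotation, adjusted p = 0.254). In the same permutation test, the 21U-RNA call ended at 1000 bp (1.96-fold, adjusted p = 0.0655), among the stronger 50% of peaks (1.66-fold, adjusted p = 0.276) and among peaks matched in both replicates (1.79-fold, adjusted p = 0.216). At 150 bp the fold rose to 108 for SL RNA, 70.7 for snRNA, 43.7 for snoRNA and 38.8 for tRNA genes, and at 1000 bp it fell to 19.7, 13.1, 10.3 and 7.76.

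**Figure D1:**
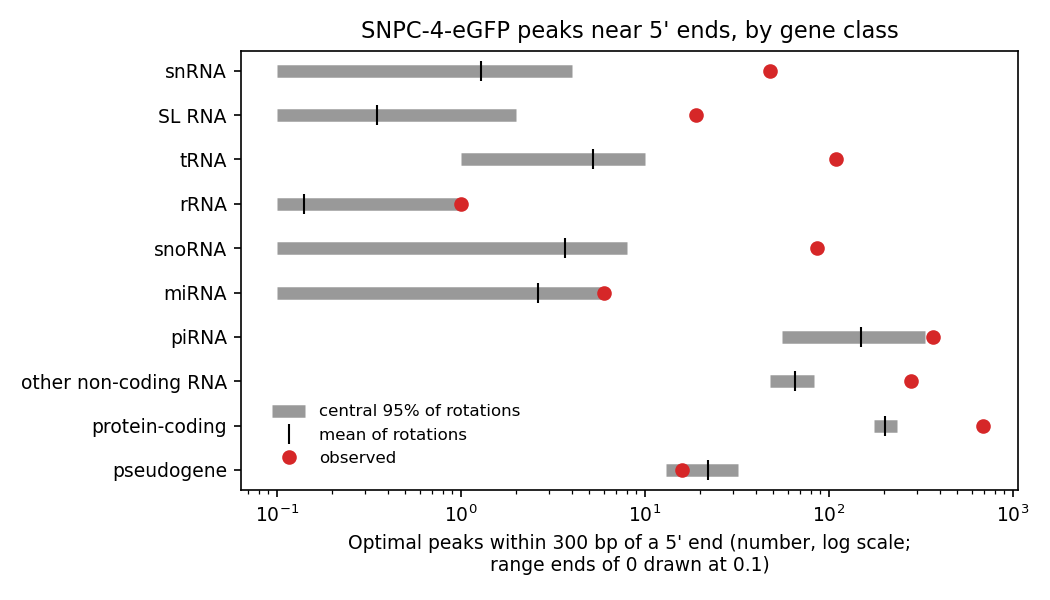
Number of optimal SNPC-4-eGFP peaks with a summit within 300 bp of a 5' end of each gene class (points, log axis), with the mean (black tick) and the central 95% (grey bar) of 10000 rotations. The points for SL RNA (19), snRNA (48), snoRNA (86) and tRNA genes (109) stand to the right of their grey bars.

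Counted by gene, 18 of 31 SL RNA genes (58.1%, interval 39.1 to 75.5) had a peak. So did 43 of 99 snRNA genes (43.4%), 84 of 346 snoRNA genes (24.3%), 19.4% of 612 tRNA genes and 1258 of 15363 21U-RNA genes (8.19%). Protein-coding genes stood at 4.32% (862 of 19973), and all 5 of these classes were higher by Fisher's exact test, with adjusted p from 3.59e-40 for tRNA to 5.79e-17 for SL RNA genes and 1.4e-50 for 21U-RNA genes. The 1258 21U-RNA genes lay beside 368 peaks, so the test of that class counts many peaks more than once. Pseudogenes were lower, at 0.752% (exact test, adjusted p = 4.23e-21). Other non-coding RNA genes, at 4.23%, did not differ (exact test, adjusted p = 0.77), and the alternatives went both ways. They were higher at 150 bp (odds ratio 1.61, exact test, adjusted p = 1.47e-08) and without replicate 2 (1.21, adjusted p = 0.0126), and lower at 500 bp (0.842, adjusted p = 0.00551), at 1000 bp (0.792, adjusted p = 2.13e-05) and against all other genes (0.669, adjusted p = 1.83e-12). The 21U-RNA share ended as a call among the stronger 50% of peaks (odds ratio 0.883, exact test, adjusted p = 0.13) and among peaks matched in both replicates (1.14, adjusted p = 0.108). Without replicate 2 the 21U-RNA share was 15.1% and the odds ratio 5.85, against 1.98 with both and 1.65 without replicate 1.

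Within the SL RNA genes, 18 of 19 SL2 genes (94.7%) had a peak, including 12 of the 13 with unique upstream sequence. None of the 12 SL1 genes had one, but these cannot be compared with SL2 genes. SL1 and SL2 RNAs donate the leader sequences that are trans-spliced onto worm mRNAs. Peaks at SL2 genes ranged from 41.9 to 1277 in signal with a median of 265, and the strongest after sls-2.4 and sls-2.8 was at sls-2.2 (966). No relaxed list held a peak at an SL1 gene. All 12 SL1 genes shared a 36-mer of their 200 bp upstream sequence with another place in the genome, and in 11 of them every upstream 36-mer was shared, so a read of that length could not be placed uniquely there.

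Among snRNA genes, the U5 family had the highest share with a peak, 10 of 11 genes (90.9%) against 37.5% of the other snRNA genes (adjusted p = 0.00538, Fisher's exact test). Its strongest member was F38E11.10 at 835. U1 genes had a peak in 8 of 12 cases (66.7%), U4 in 4 of 5 (80%), U6 in 8 of 22 (36.4%) and U2 in 5 of 18 (27.8%). None of these 4 families differed from the rest after adjustment, nor did the 31 genes placed in no family (8 with a peak, exact test, adjusted p = 0.0838). The strongest U1 gene was sup-6 (841) and the strongest U4 gene, C52E4.8, stood at 778. Of the 99 snRNA genes, 42 share a 36-mer of their upstream sequence with another place in the genome, which can lower a family's count. Among the other 57, 6 of 7 U5 genes had a peak against 50% of the rest and did not pass (exact test, adjusted p = 0.336), while the 25 genes placed in no family were lower, at 32% against 71.9% (exact test, adjusted p = 0.0215). The U5 and other family counts were drawn up after the class counts were seen.

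tRNA genes passed into the optimal list at different rates by place. Inside the 21U-RNA-rich windows of chromosome IV, 35 of 41 tRNA genes (85.4%) had a peak, against 14.7% of tRNA genes elsewhere (odds ratio 33.8, Fisher's exact p = 2.36e-21). In the pooled relaxed list the shares were 92.7% inside and 69.9% elsewhere (Fisher's exact p = 0.00103), and 437 of all 612 tRNA genes (71.4%) had a peak. That list was deposited as peaks and background, and 26.5% of protein-coding genes also had a peak in it. No chance share was computed for it, so a peak found only there is not by itself evidence of binding. By chromosome, the share with an optimal peak was 60.6% on IV (43 of 71, exact test, adjusted p = 9.93e-16). Elsewhere it ran from 9.38% on III to 26.3% on II, with 10.9% on X (30 of 276). The strongest tRNA peaks stood at C27A2.t1 on chromosome II (550.3), M01E5.t1 on chromosome I (529, a peak also near an SL RNA gene) and Y37A1B.t1 in a 21U-RNA-rich window (525). No isotype passed, and the lowest adjusted p was 0.508, for alanine tRNA genes (12 of 34, 35.3%). The share outside the windows fell to 8.41% without replicate 2 and to 3.85% when peaks had to be matched in both replicates, while the shares inside were 87.8% and 82.9%.

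Signal ranked the classes in a similar order. Median signal was 242 at SL RNA, 109.5 at snRNA and 68.9 at snoRNA peaks, against 44.0 at protein-coding peaks, which is 5.50, 2.49 and 1.57 times as high. Each of these 3 differences had an adjusted p of 4e-05, which rests on the smallest p that the permutation test can give. Peaks assigned to 21U-RNA genes were weaker, with a median of 36.8 (permutation test, adjusted p = 4e-05), and so were peaks with no annotated 5' end within 300 bp (41.5, adjusted p = 0.0426). The tRNA median of 48.9 did not pass (permutation test, adjusted p = 0.0553), and its upper quartile was 143. With the signal of replicate 1 alone, the permutation test changed: the direction turned for 21U-RNA peaks (2.41 above protein-coding peaks, adjusted p = 0.00134) and for peaks with no 5' end nearby (1.33 above, adjusted p = 0.0293), and tRNA (3.08 above, adjusted p = 0.0155) and other non-coding RNA peaks (3.87 above, adjusted p = 0.0012) passed.

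**Figure D2:**
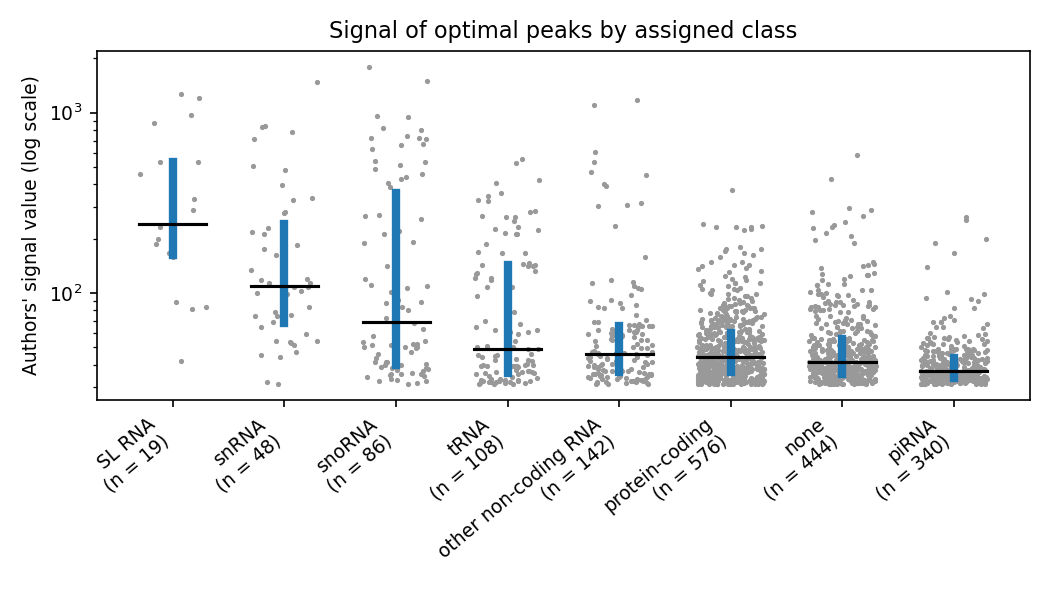
The authors' signal value (log axis) of each optimal peak by assigned class, with the median (black line) and the quartiles (blue bar). Medians fall from 242 at SL RNA genes to 36.8 at 21U-RNA genes, labelled piRNA.

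At snRNA, SL RNA, snoRNA and tRNA genes, summits lay at set places relative to the 5' ends. Median offsets were -44 bp at snRNA, -49 bp at SL RNA and -43.5 bp at snoRNA genes, where negative is upstream, and 89.5% of snoRNA summits lay upstream. At tRNA genes the median was 3 bp with quartiles of -24 and 24 bp, so summits lay over the start of the gene. At protein-coding genes the median was -144 bp with quartiles of -209.5 and -64 bp, a spread over the 300 bp searched upstream. Summits near 21U-RNA genes had a median of 0 bp and lay upstream in 48.9% of cases. Most of these genes lie close together in the 21U-RNA-rich windows. There, summits rotated within the windows lay beside one in 306 of 505 cases on average. These offsets therefore cannot show whether binding favours a side. By annotation, 65.1% of all summits were intergenic, 357 summits lay in introns, 6.12% in non-coding exons, 3.48% in small RNA genes, 2.92% in 5' UTRs, 1.18% in 3' UTRs and 1.12% in coding exons.

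**Figure D3:**
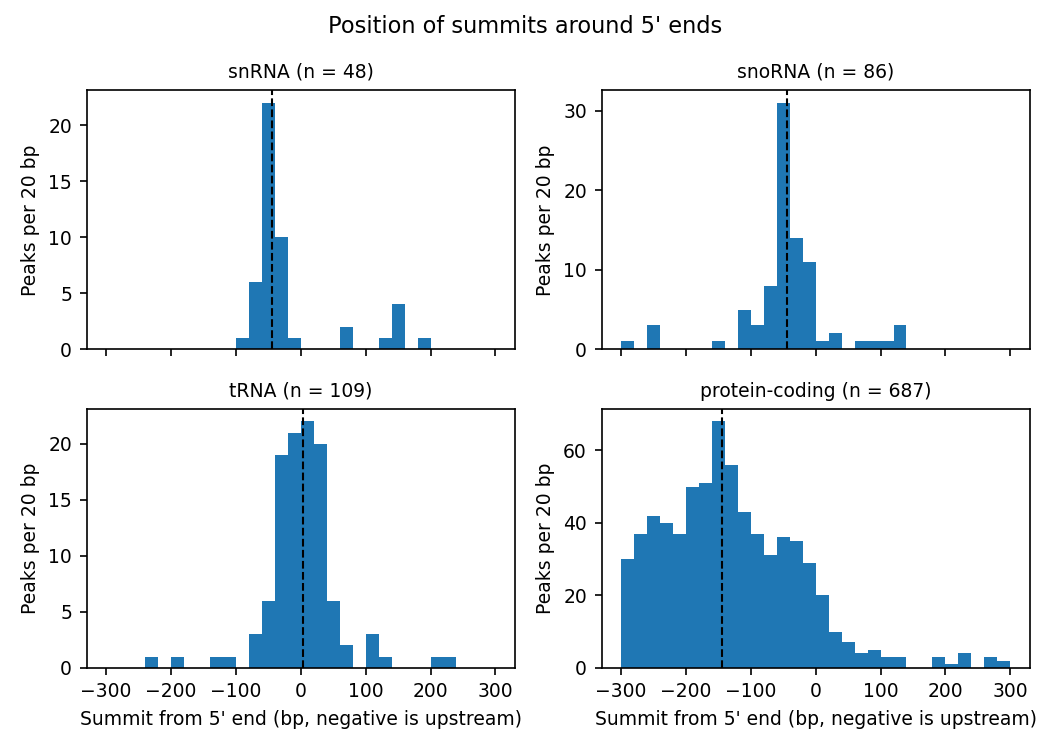
Distance of each optimal summit from the nearest 5' end of snRNA, snoRNA, tRNA and protein-coding genes, in bins of 20 bp, with the median as a dashed line. snRNA and snoRNA summits gather near -44 bp, tRNA summits near 3 bp, and protein-coding summits spread around -144 bp.

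Among the 8-mers that stood out at the summits, some were shared between classes. At snRNA peaks, CGGAACCC was found within 100 bp of 31.2% of summits against 3.12% at the flanks, and at snoRNA peaks it was found at 22.1% against 0%. At tRNA peaks the first was GGGTTCGA, at 31.5% against 1.39%, which resembles the B box, the internal promoter of tRNA genes. At protein-coding peaks AAACGCGC stood at 13.2% against 0.260%, and AGACGCAG at 12.3% against 0.955%. AGACGCAG was also found at 15.5% against 1.35% of peaks with no 5' end nearby and at 9.86% against 0% of other non-coding RNA peaks. A 22 bp element learned upstream of snRNA, SL RNA and snoRNA genes with a peak read TGACCGGCGGAACCCGCGAGGT at its most frequent bases, with the core GCGGAACCCG. It was found in 84 of 145 upstream sequences, centred at a median of -58 bp with quartiles of -59.2 and -57 bp. This element was carried by 75% of snRNA, 52.6% of SL RNA and 46.5% of snoRNA peaks, the classes it was learned from. It was also carried by 21.2% of peaks with no 5' end nearby (flanks 5.86%, exact McNemar test, adjusted p = 1.64e-09) and by 8.53% of 21U-RNA peaks (flanks 2.35%, adjusted p = 0.00207). Shares of 2.78% at tRNA and 9.20% at protein-coding peaks did not differ from the flanks (exact McNemar test, adjusted p = 0.999 and 0.227). At snoRNA genes, peaks with the element had a median signal of 329 and those without had 46.5, while at SL RNA genes the medians were 237 with it and 456 without, and neither difference was tested.

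Chromosome IV, which carries 95.8% of the annotated 21U-RNA genes, held 714 peaks, or 40.1% of the list (interval 37.8 to 42.4), against 17.4% of the genome's length. The ratio of 2.30 had an adjusted p of 8.24e-111 by the exact binomial test. Peaks lie in groups and are not independent, so the binomial p-values of the chromosomes describe counting error only. Chromosome IV held 40.8 peaks per Mb. The other 5 chromosomes held 12.9 per Mb together, with 12.7 on I, 15.4 on II, 16.4 on III, 10.9 on V and 10.4 on X. By the same exact test, the shares of I (ratio 0.717, adjusted p = 2.77e-07), II (0.870, adjusted p = 0.0231), V (0.616, adjusted p = 5.83e-18) and X (0.585, adjusted p = 1.06e-17) were below their lengths and that of III was not (0.923, adjusted p = 0.203). These shares fall as that of chromosome IV rises, and the 5 chromosomes were not tested against each other. On ce10 the ratio for chromosome IV was also 2.30.

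Most of the excess on chromosome IV lay in 2 regions dense in 21U-RNA genes, the piRNA genes of this species. The 54 windows of these regions cover 5.4 Mb and held 505 peaks, 28.4% of the list (interval 26.3 to 30.5), where rotated peaks averaged 12.3% (permutation by rotation, two-sided p = 0.0032). Peak density was 93.5 per Mb in the windows, 17.3 per Mb on the rest of chromosome IV and 12.9 per Mb on the other 5 chromosomes. Region 2, from 13600001 to 17300000, held 445 peaks, and 10.7% of its 11510 21U-RNA genes had one. Region 1 was made of 17 windows between 4800001 and 6600000, without the window from 6300001, which has only 44 21U-RNA genes. It held 60 peaks, and 0.421% of its 2614 21U-RNA genes had one. Across the 175 windows of chromosome IV, which are not independent, Spearman's rho between peaks and 21U-RNA genes was 0.681, above the central 95% of rotations (upper end 0.622). Of the 505 peaks, 331 were assigned to 21U-RNA genes, 43 to protein-coding genes, 34 to tRNA, 10 to snRNA, 9 to snoRNA and 4 to SL RNA genes, and 61 had no 5' end nearby. Inside the windows 8.80% of 21U-RNA genes (1243) had a peak, where peaks rotated within the windows gave 787 on average (permutation p = 0.0002). The 2 regions went opposite ways in this permutation test, with 1232 genes against 824 in region 2 and 11 against 55.7 in region 1 (p = 0.0002 each).

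**Figure D4:**
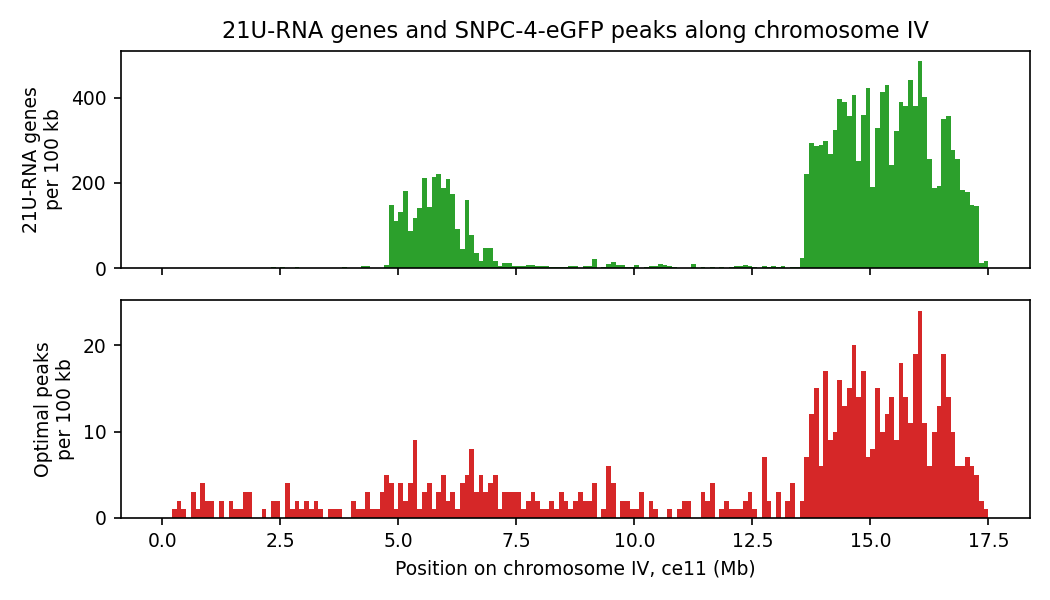
Number of annotated 21U-RNA genes (upper panel) and of optimal peaks (lower panel) in each 100 kb window of chromosome IV, against position in Mb on ce11. Peaks rise with 21U-RNA genes in the right-hand region, which held 445 peaks, and less so in the left-hand region, which held 60.

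The strongest peaks of the 2 regions stood at snoRNA genes: 741 beside Y67A10A.14 in region 2 and 438 beside T08B6.64 in region 1. The first of these also lay within 300 bp of 21ur-10179 and 21ur-7591, and the third 21U-RNA gene by signal, 21ur-1058, lay beside a tRNA peak of 424. In the list of replicate 1 alone, cut at the same length, 46.3% of peaks fell in the windows, against 26.1% in replicate 2. The share of windowed 21U-RNA genes with a peak was 2.27% among the stronger 50% of peaks and 16.3% without replicate 2. Among the stronger 50%, 321 windowed genes had a peak against 354 in rotations within the windows (permutation p = 0.29), and among peaks matched in both replicates it was 366 against 378 (permutation p = 0.767). Counted by peaks in the windows, those beside a 21U-RNA gene were more than in rotations in the optimal list (354 against 306, permutation p = 0.002) and fewer among the stronger 50% (110 against 138, permutation p = 0.0004) and the matched peaks (122 against 147, permutation p = 0.0042). In region 1 these last 2 counts were 8 against 23.6 and 7 against 24.6 (permutation p = 0.0002 each). In region 2 they were 102 against 118 (permutation p = 0.021) and 115 against 127, which did not pass (permutation p = 0.096). Peaks of other genes were not left out of these counts of peaks, so class was not held constant. Counted by genes in each replicate's own list, there was an excess in both, with 2309 against 1263 in replicate 1 and 1068 against 727 in replicate 2 (permutation p = 0.0002 each).

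The core motif CTGTTTCA, known upstream of 21U-RNA genes, lay within 100 bp of 153 of the 505 summits in the windows, or 30.3% (interval 26.3 to 34.5). At points 1000 bp to each side the share was 18.4% (exact McNemar p = 3.21e-06 and 1.03e-05), and outside the windows it was 0.470% (Fisher's exact p = 4.54e-83). The windows were chosen for dense 21U-RNA genes, so the contrast with peaks outside describes the windows and not binding. The same word ranked first among all 8-mers at 21U-RNA peaks. Peaks in the windows with the motif had a lower median signal than those without, 36.6 against 46.2 (permutation p = 2e-05). This took in peaks of all classes, such as 34 tRNA peaks, and tRNA genes with a peak there had a median signal of 167. Class was not held constant, so the difference cannot be credited to the motif. Inside the windows, 21U-RNA genes with the motif in the 80 bp upstream had a peak as often as those without, 8.80% each (odds ratio 1.00, Fisher's exact p = 1). Outside the windows the shares were 0.913% and 1.27%. In the windows 1243 genes lay beside 354 peaks, so neighbours with and without the motif share peaks. The equal shares therefore cannot decide whether the motif matters. The excess over the flanks ended among peaks matched in both replicates (18.9%, exact p = 0.342) and with 1 mismatch allowed (61.98%, exact p = 0.0822).

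Protein-coding genes with a peak included many ribosomal protein genes. Of 78 such genes, 32 (41.0%) had a peak, against 4.17% of other protein-coding genes (odds ratio 15.98, adjusted p = 2.12e-22, Fisher's exact test), led by rpl-18A (242), rpl-3 (231) and rpl-29 (224), with summits 287, 280 and 262 bp upstream. The share depended on the distance, at 3.85% within 150 bp (exact test, adjusted p = 0.423) and 79.5% within 500 bp (adjusted p = 1.11e-61). Spliceosome protein genes had a peak in 10 of 40 cases (25%, exact test, adjusted p = 4.16e-05), with prp-40 (65.9), sap-140 (52.0) and the Sm protein gene snr-3 (46.1) at the top. That call ended among the stronger 50% of peaks (exact test, adjusted p = 0.246). Genes of the Integrator complex, which processes the 3' ends of snRNAs, had a peak in 3 of 11 cases: ints-4 (84.6), ints-11 (41.4) and ints-8 (37.7), with an adjusted p of 0.0305 by Fisher's exact test. Histone genes also passed, with 8 of 72 (11.1%, exact test, adjusted p = 0.0305), led by his-37 (87.4) and the pair his-67 and his-68, which share a peak of 84.8. The 8 histone genes rest on 5 peaks, since 3 pairs of them share one, so the test counts some peaks more than once. The Integrator call was lost in 5 and the histone call in 7 of 7 alternatives.

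Of 4 genes in the list drawn up as single-copy RNA genes of RNA polymerase III, 3 had a peak (adjusted p = 0.00288, Fisher's exact test): rpr-1, mrpr-1 (536), the RNA of RNase MRP, and yrn-1 (115), a Y RNA. The fourth, rncs-1, had none, and it was named outside the rule after the values were seen. Which polymerase transcribes each member was not examined, so rncs-1 is not shown to be an exception among genes of RNA polymerase III. Germ line marker genes had a peak in 6 of 18 cases (33.3%, exact test, adjusted p = 0.000377): rme-2 (140.3), the yolk receptor of oocytes, oma-1 (38.1), mex-5 and rec-8 (a shared peak of 40.05), and him-3 and pgl-1 (a shared peak of 33.9). oma-1 and him-3 were chosen after their values were seen. All 6 genes lie on chromosome IV, and the call ended without replicate 1 (exact test, adjusted p = 0.31), at 150 bp (adjusted p = 0.133), among the stronger 50% of peaks (adjusted p = 0.597) and among peaks matched in both replicates (adjusted p = 0.141). Among markers of other tissues, peaks stood at 1 of 65 sperm genes (spe-48, 43.2), 0 of 16 intestine, 0 of 12 body wall muscle, 0 of 14 neuron and 0 of 12 hypodermis genes. None of these 5 lists passed (lowest adjusted p = 0.724, Fisher's exact test). At a share of 4.32% among all protein-coding genes, a count of 0 in a list of 12 to 16 genes does not show fewer peaks.

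Genes of SNAPc itself and of piRNA transcription had a peak in 2 of 13 cases, snpc-4 (131) and snpc-3.4 (36.8), and did not pass (adjusted p = 0.177, Fisher's exact test). The peak of snpc-4 stood 210 bp upstream of the gene. As the transgene carries snpc-4, such a peak can come from the endogenous gene, the transgene or both. At unc-119, which the transgene also carries, no optimal peak was found, and the pooled relaxed list held none within 300 bp of its 5' end, though 6 of its peaks touched the gene (highest signal 11.3). In snpc-4 itself 6 touched the gene (highest 16.1). The piRNA pathway list had 1 of 17 members with a peak, pgl-1 (adjusted p = 0.724, Fisher's exact test), and the pseudogene prg-2 had a peak of 90.4. RNA polymerase and general factor genes had 5 of 42, led by rpb-11 (71.1), taf-11.3 (54.4) and rpb-12 (48.0), and did not pass (adjusted p = 0.0721, Fisher's exact test).

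Agreement between the replicates varied by class, which was not tested. In replicate lists cut at 1781 peaks, all 19 SL RNA peaks, 85.4% of snRNA and 69.8% of snoRNA peaks were matched within 200 bp in both replicates. The share was 49.1% for tRNA, 46.4% for protein-coding and 31.2% for 21U-RNA peaks. By median signal these classes stand in the same order, from 242 at SL RNA to 36.8 at 21U-RNA peaks. The lists were cut by signal and signal was not held constant, so class and signal cannot be told apart here. Over the whole list, 63.2% of peaks were matched in replicate 1 and 77.9% in replicate 2, and 845 peaks (47.4%, interval 45.1 to 49.8) in both, where rotations averaged 0.0158%. In the full relaxed lists the share matched in both was 97.02%. Across the 1728 peaks matched there, which are not independent replicates, Spearman's rho of signal between replicates was 0.384 and Pearson's r of log2 signal was 0.651. The 2 replicates alone allow no test between samples.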

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

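Among the tests given here, that of peaks of other genes, that of the stronger peaks without them, those by rotation within the windows, those of the motif at matched peaks and at 21U-RNA genes, and the counts of pooled peaks below the optimal list were chosen only after the results were seen.

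Pooled relaxed peaks that rank just below the optimal list, from 1782 to 3562 by signal, are outside the optimal list, on which the comparisons above rest except where a relaxed list is named. They drew attention because they lay beside tRNA, snoRNA and snRNA genes and in the 21U-RNA-rich windows more often than rotated peaks. Of these peaks, 77 lay within 300 bp of a tRNA 5' end, where rotations averaged 5.40. Beside snoRNA genes there were 18 (rotation mean 3.61), and beside snRNA genes there were 8 (rotation mean 1.45), while beside SL RNA genes there were 0 (rotation mean 0.316). Counts were also above the central 95% of rotations beside protein-coding (428, rotation mean 200), other non-coding RNA (177, rotation mean 66.3), 21U-RNA (646, rotation mean 166) and miRNA genes (10, rotation mean 2.68). In the 21U-RNA-rich windows there were 703 (rotation mean 245, upper end of the central 95% of rotations 688).

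The concentration of optimal peaks in the 21U-RNA-rich windows of chromosome IV, 28.4% of the list, was weighed against 2 technical explanations and 1 about its sequence. Peaks of other genes in the windows are argued against: with peaks near snRNA, SL RNA, tRNA, rRNA, snoRNA or protein-coding 5' ends left out, 45.1% of the remaining 859 peaks lay in the windows, and 43.5% was the upper end of the central 95% of rotations. Weak peaks near the reporting threshold are argued against for the windows as a whole, by narrow margins, since 25.6% of the stronger 50% of peaks lay there and 24.7% was the upper end of the central 95% of rotations (38.1% and 36.7% with peaks of other genes left out), but they stay open for the peaks beside 21U-RNA genes: 110 of the stronger peaks in the windows lay beside one, fewer than the 138 in rotations within the windows (permutation p = 0.0004). By region, this was 102 against 118 in region 2 (permutation p = 0.021) and 8 against 23.6 in region 1 (permutation p = 0.0002). Peaks of other genes were not left out of these counts: of the 228 stronger peaks in the windows, 130 remained without them. Class was not held constant, so the deficit cannot be credited to the strength of the peaks. Binding beside the 21U-RNA upstream core motif stays open for part of the peaks: 30.3% of summits in the windows carried the motif against 18.4% at the flanks, but among peaks matched in both replicates the excess did not pass (exact p = 0.342). In the windows, 21U-RNA genes with and without the motif had a peak equally often (8.80% each). That comparison cannot decide the question, because neighbouring genes share peaks. Open chromatin and the missing control library were not tested, and with 1 group no biological explanation was tested.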

How the results depend on the processing

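Of the alternatives run, those on peaks matched in both replicates' lists, and all of those on SL2 RNA genes, tRNA genes in the windows and 21U-RNA genes in the windows, were chosen only after the results were seen. For 60 results, 403 alternatives were run, and 349 kept their side of the threshold (or stayed within the spread). Of the others, 26 lost the threshold, 13 gained it and 10 moved, while 5 turned direction where the main result or the alternative passed. Where neither passed, a change of direction was counted among the 349. An example is the signal difference of other non-coding RNA peaks, 2.01 in the main setting and -0.678 with a replicate left out. The chromosome IV ratio (2.19 to 3.19) and the share of peaks in the 21U-RNA-rich windows kept their calls in each alternative run, and the number of enriched classes stayed between 6 and 8, against 7. Where results changed, the cause was not tested.

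Folds of class enrichment for miRNA genes passed at 150 bp (4.46), among the stronger 50% of peaks (4.66), among matched peaks (4.07) and without replicate 2 (2.59), but not without replicate 1 (2.31). The 21U-RNA fold no longer passed at 1000 bp (1.96), among the stronger 50% (1.66) and among matched peaks (1.79), and the pseudogene fold passed at 1000 bp (0.566). As odds ratios of gene share, other non-coding RNA genes stood at 1.61 at 150 bp, 0.842 at 500 bp, 0.792 at 1000 bp, 0.669 against all other genes and 0.968 to 1.21 with a replicate left out, passing as higher at 150 bp and without replicate 2 and as lower at 500 bp, 1000 bp and against all other genes. The 21U-RNA ratio was 0.883 among the stronger 50% and 1.14 among matched peaks. Against all other genes, miRNA genes stood at 0.377 and passed as lower, the opposite direction to their folds of class enrichment.

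Of the 15 gene lists, 6 passed, and fewer passed in each alternative: 3 at 150 bp, 2 among the stronger 50%, 3 among matched peaks and 4 each at 500 bp, at 1000 bp, without replicate 1 and without replicate 2. At 150 bp, odds ratios that no longer passed were 2.96 for histone, 2.01 for ribosomal protein and 6.27 for germ line genes. At 500 bp they were 2.09 for histone and 6.26 for Integrator genes, and at 1000 bp 2.31 and 4.78. Among the stronger 50% they were 1.75 for histone, 4.02 for Integrator, 3.27 for spliceosome and 2.36 for germ line genes. Among matched peaks they were 3.42 for histone, 4.55 for Integrator and 5.70 for germ line genes. With a replicate left out, ratios ran from 2.36 to 2.47 for histone, 2.73 to 12.8 for germ line and 3.29 to 18.2 for Integrator genes.

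Median signal differences from protein-coding peaks, with 1 replicate's signal at a time, ran from -9.74 to 2.41 for 21U-RNA, -3.82 to 1.33 for peaks with no 5' end nearby, 3.08 to 3.14 for tRNA and -0.678 to 3.87 for other non-coding RNA peaks. That last class passed without replicate 2 (3.87) and when each peak counted in all its classes (7.10), and peaks with no 5' end nearby no longer passed by rank (-103.5). The ratio to length of chromosome II, 0.870 in the full list, no longer passed among the stronger 50% (0.929). That of chromosome III, 0.923, ranged from 0.637 to 0.927 with a replicate left out, and passed as lower at 0.637. Both are ratios of shares that fall when chromosome IV's share rises. The share of peaks matched in both replicates was 44.9% within 100 bp, 32.8% for intervals sharing at least 50%, 97.02% in full relaxed lists and 27.6% in lists cut at 50% of the length, the last 2 by construction of longer or shorter lists. Rank correlation of signal was 0.425 within 100 bp and 0.583 among the stronger 50%, and Pearson's r was 0.651. The core motif's excess no longer passed with 1 mismatch (61.98%) and among matched peaks (18.9%). Without read depth, peaks below the lists' signal limits cannot be judged.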

Other observations

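Of the tests in this part, those of chance overlap and of the relaxed list at tRNA genes and that of the element by place were chosen only after the result was seen.

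Some of the strongest peaks lay near no annotated 5' end, and all peaks named here were chosen after their values were seen. The strongest stood on chromosome III from 11463801 to 11464168, in the 3' UTR of bed-2, with a signal of 582 (262 in replicate 1 and 322 in replicate 2). The next stood in introns of Y105C5A.15 (428) and Y46G5A.34 (296). Of the 444 peaks with no 5' end within 300 bp, the strongest 10% were 44 peaks with signals from 88.96 to 582, of which 18 were in introns, 23 were intergenic and 17 lay in the 21U-RNA-rich windows.

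For these 44 peaks, a signal from 1 replicate only is argued against, since 100% of them were matched in both replicates' lists. The share was 41.2% for the other 400 peaks. Those are weaker and the lists were cut by signal, so this contrast does not bear on the question. An annotated small RNA gene just beyond 300 bp is argued against as a general account: 6.82% had one within 1000 bp, with an upper bound of 18.7%. Small RNA genes missing from the annotation stay open as a hypothesis: 40.9% of the 44 peaks carried the learned promoter element, against 19% of the weaker ones (Fisher's exact p = 0.00159). That holds for part of the peaks, as 16 of 27 outside the windows carried the element and 2 of 17 inside them did (Fisher's exact p = 0.00206). With 1 group, no biological explanation was tested, and no RNA data were used.

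The higher share of tRNA genes with a peak in the 21U-RNA-rich windows was weighed against 2 technical explanations. Chance overlap with the dense peaks there is argued against: 35 tRNA genes had a peak, where rotations within the windows averaged 2.28 and had 6 as the upper end of their central 95%. Upstream sequence on which short reads cannot be placed uniquely is argued against too. Among tRNA genes with unique upstream 36-mers, 90.6% had a peak in the windows (29 of 32) and 15.7% elsewhere (Fisher's exact p = 1.05e-18). The tRNA genes themselves, over whose starts the summits lay, were not searched for shared 36-mers, so the placing of reads there stays open. In the pooled relaxed list, which holds background as well as peaks, 92.7% of tRNA genes in the windows and 69.9% of the others had a peak (Fisher's exact p = 0.00103). The smaller gap there cannot be interpreted, since the share in the windows is near its upper limit and no chance share was computed. What sets these tRNA genes apart stays open, including open chromatin in the windows, and no biological explanation was tested with 1 group.

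A hypothesis on snoRNA genes was that those inside a host gene are made from the host's promoter. Of 183 snoRNA genes inside a protein-coding gene on the same strand, 13.7% had a peak, against 36.2% of the other 163 (Fisher's exact p = 1.34e-06). Of those inside a gene on the opposite strand, 42.4% of 33 had one, and 34.6% of the 130 outside genes did. The counts are consistent with the hypothesis, which was tested on the same peaks as the rest, and 25 of the hosted snoRNA genes had a peak within 300 bp, which was not assigned to the snoRNA gene or the host by any test.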
